A study of Mus musculus with 28 samples.

How the data were processed

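The series holds 28 RNA sequencing samples of mouse kidney cells in 10 groups, by the labels 2 cell types (endothelial and proximal tubular) crossed with sham, untreated ischemic injury, and injury treated with scrambled miRNA, exosomes or a miR-486-5p mimic. Per the labels, endothelial cells were taken with CD31 microbeads and proximal tubular cells by microdissection after enzymatic digestion, and RNA came from 3 male mice in each group, so each library was treated as 1 animal. The same library numbers occur in both cell types, and the labels do not say whether they mark the same mouse. Fits over both cell types took the 16 libraries as independent. The mimic groups hold 2 libraries, and the series design gives n = 2 for them. Libraries were poly(A) selected and sequenced on a NextSeq 500, per the labels. Per-sample files were analysed here for 6 groups, the scrambled-miRNA, exosome and mimic groups of both cell types, in 16 libraries. Sham and untreated samples were used only through the 12 comparison tables, and per the labels they are reanalyses of samples from an earlier series.

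Per the submitters' processing notes, Salmon 0.13.1, DESeq2 and GRCm38 were used; the notes give no order or settings. The estimated counts per transcript were made by the authors with Salmon and deposited unnormalized, so they can be fractional. TPM values in the same files were computed by the authors from the estimated counts and effective lengths, per the file headers. Effective length in the deposited files, per the file headers a Salmon column, equals transcript length less a constant for most transcripts. The log2 fold changes and their standard errors were computed by the authors with DESeq2 column names, per the file headers, with the first-named group over the second. The p-value and adjusted p columns were likewise computed by the authors and deposited in those tables. The base mean, a signal averaged over normalized libraries by the authors, is the same in the 6 deposited tables of a cell type, so those libraries had been normalized together. Direction was checked by subtracting tables: differences correlated with the third table at r = 0.850 and 0.946 in endothelial and 0.971 and 0.887 in tubular cells, and with the fits made here at 0.756 to 0.914. Folds in the tables appear shrunken: in tubular mimic against sham the median of absolute fold over standard error was 0.136, where the p-values imply 0.730.

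The 136202 transcripts of each file were summed to the 53392 genes that their own names give, and the GENCODE M21 annotation, which most names match exactly, supplied positions and 3' UTRs. Gene sums of estimated counts were rounded to whole numbers for the tests, and gene TPM is the sum over transcripts. Depth ran from 8.27 to 25.3 M reads per library. Each cell type was fitted on its own with edgeR 4.0.16 in R 4.3.3, using TMM normalization, filterByExpr (minimum count 10, minimum total 15), and quasi-likelihood F tests, with Benjamini-Hochberg adjustment at 0.05. This left 16316 endothelial and 14913 tubular genes, and a fit of both cell types for interaction terms and the cell type effect held 17143. Across these, 9 comparisons were tested. Common dispersion was 0.0894 in endothelial and 0.0774 in tubular cells. Standard errors of single-gene log2 folds are those of the fit, and log2 CPM used a prior count of 2. Standard errors of list medians and of median z scores are over genes. Where all libraries of a group held no read, a bound was taken from 3 reads over the group.

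The procedure was tested on simulated data with the libraries' own dispersions, 100 genes changed at each size. The changed genes were drawn only from those averaging more than 100 reads, and genes were simulated independently. Recovery of genes with fewer reads, or with correlated genes, is therefore not known. At a log2 fold of 1, 56 of 100 were recovered in tubular exosomes against scrambled miRNA (14470 genes), 34 in tubular mimic against scrambled miRNA (14438) and 34 against exosomes (14465). The endothelial recoveries were 17 (15811 genes), 10 (15816) and 12 (15780) in the same order, the interactions had 13 (16512) and 7 (16495), and the cell type comparison 79 (16496). At a log2 fold of 2 the recoveries were 97, 94 and 95 in tubular cells, 94, 92 and 88 in endothelial cells, 81 and 61 for the interactions and 99 for the cell type.

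There were 27 gene lists fixed before the files were opened: reported miR-486-5p targets, PI3K-AKT-FoxO pathway, FoxO-responsive genes, tubule injury, proximal tubule, fatty acid oxidation, NF-kB and cytokines, p53 and apoptosis, cell cycle, hypoxia and glycolysis, NRF2, immediate early and heat shock, unfolded protein response, interferon response, matrix and TGF-beta, endothelial activation, endothelial identity, thick ascending limb, distal and collecting duct, podocyte, macrophage, neutrophil, lymphocyte, fibroblast and pericyte, platelet and megakaryocyte, erythroid, and mitochondrially encoded genes. Lists with at least 5 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, which compares a list with all other genes, again with the correlation estimated from the data, and with fry. The fry p-value asks whether a list's genes move on balance one way, its mixed p-value whether they move either way, and neither compares them with other genes. Adjustment was over the lists of a comparison. Counts adjusted over the list alone correct the single-gene p-values within that list. For the deposited tables the list test used z scores from the authors' p-values and the sign of the fold; fold over standard error had been chosen earlier and is kept as an alternative, since the deposited folds are shrunken. The correlation for these was estimated from the libraries analysed here.

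Genes named in the report follow a fixed rule. In each comparison it names the 5 top genes each way by fold among those passing with a mean of at least 100 reads, leaving out predicted genes without a symbol of their own. For lists with at least 2 genes passing it adds up to 4 members. Foxo1, Havcr1, Lcn2, Pecam1 and Slc34a1 are always eligible, and where fewer than 4 genes pass all are named; from the deposited tables fewer are given. Some genes that the rule would name are not reported here. Injury signatures took the genes called in the authors' tables of untreated injury against sham, up to 300 each way. Sites for the miR-486-5p seed were counted in 3' UTRs of the M21 annotation and compared with 419 other words of the same bases, which are all such words, in place of random shuffles. The similarity of exosome and mimic effects was set against 20 simulations with a shared control.

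Alternatives were DESeq2 1.42.0 in place of edgeR, RLE normalization, no low-count filter, an offset for average transcript length, only the 2 groups compared, a block for replicate number, and each library left out in turn. The mimic groups have 2 libraries, so their values without 1 library rest on 1. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots. Reads, isoforms and small RNA levels were not analysed here, so the amount of miR-486-5p in the cells is not known from these files.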

Results

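Messenger RNA was sequenced from endothelial cells and proximal tubular cells of male FVB mice with ischemic acute kidney injury. Endothelial cells had been drawn from digested kidneys with microbeads against CD31, and tubular cells had been microdissected. The labels place 28 samples in 10 groups. For each of the 2 cell types there were sham mice, injured mice without treatment, and injured mice given scrambled miRNA, exosomes or a mimic of miR-486-5p, a miRNA reported to repress Foxo1. Each group held 3 libraries, except the mimic groups, which held 2; the series design gives these as n, while the extraction notes speak of 3 mice in each group. The scrambled-miRNA, exosome and mimic groups were analysed from the deposited estimated counts of 16 libraries, and the sham and untreated groups only through the authors' deposited comparison tables. In endothelial cells the gene counts summed to 9.26, 8.27 and 11.8 M reads in the scrambled-miRNA libraries, 12.7, 13.6 and 12.1 M with exosomes, and 14.2 and 24.1 M with the mimic. For tubular cells the sums were 13.0, 10.2 and 8.58 M, 13.3, 13.0 and 11.3 M, and 25.3 and 23.7 M in the same order.

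The first comparison asked what the isolation of each cell type had collected. Across the 3 treatments, 11355 of 17143 genes differed between endothelial and tubular libraries by edgeR's quasi-likelihood test, 6224 higher in endothelial and 5131 higher in tubular libraries (n = 8 and 8). By camera 18 of 27 lists passed, none with an estimated correlation (adjusted p = 0.282 to 0.602). All 22 measured endothelial identity genes were higher in endothelial libraries, with a median log2 fold of 4.03. Cldn5, a tight junction protein of vessels, differed by 5.24 on the log2 scale (SE 0.29), and Pecam1, which encodes the CD31 antigen used for the sort (chromosome 11, 106654217 to 106750628, GRCm38), by 3.36 (SE 0.14). Of 30 proximal tubule transporters and enzymes, 29 were higher in tubular libraries (median -2.79), among them Slc22a30 (-3.30, SE 0.47), Miox (-3.17, SE 0.37) and Slc34a1, the main phosphate transporter of this segment (-2.94, SE 0.46). Fatty acid oxidation genes followed, with 20 of 25 higher in tubular cells and 3 lower (median -1.15), as did NRF2 antioxidant genes with 13 against 1 (median -1.0).

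The endothelial libraries also carried RNA of other kidney and blood cells. Umod, the uromodulin gene of the thick ascending limb (chromosome 7, 119462711 to 119479282), was 5.01 log2 units higher than in tubular libraries (SE 0.37) and reached 3505 to 11616 TPM in single endothelial libraries, whereas Pecam1 lay between 34.7 and 70.6 TPM there. Higher in endothelial libraries were also 9 of 10 thick ascending limb markers (median 4.14), 10 of 10 podocyte markers (4.92), 15 of 15 distal and collecting duct markers (2.12), 18 of 18 macrophage markers (2.78), 15 of 17 lymphocyte markers (5.05), 10 of 11 neutrophil markers (4.33) and 9 of 13 fibroblast and pericyte markers (2.29, with 1 lower). The distal median was 3.37 without tubular mimic library 1. Matrix and TGF-beta genes (21 of 22 higher, median 3.02), endothelial activation (19 of 19, 4.06), interferon response (22 of 22, 2.82), NF-kB and cytokine genes (23 higher, 2 lower, 2.40), immediate early and heat shock genes (19 higher, 2 lower, 1.71), tubule injury genes (15 of 24 higher, 2.80) and mitochondrially encoded genes (10 of 13 higher, 0.69) completed the 18 of 27 lists that passed. The mitochondrial list missed the threshold in 9 fits without 1 library, with medians from 0.61 to 0.69. The other 9 lists had adjusted p from 0.0645 for erythroid markers to 0.780 for hypoxia and glycolysis, with the unfolded protein response at a median of -0.16 and a mean of 0.08.

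**Figure D1:**
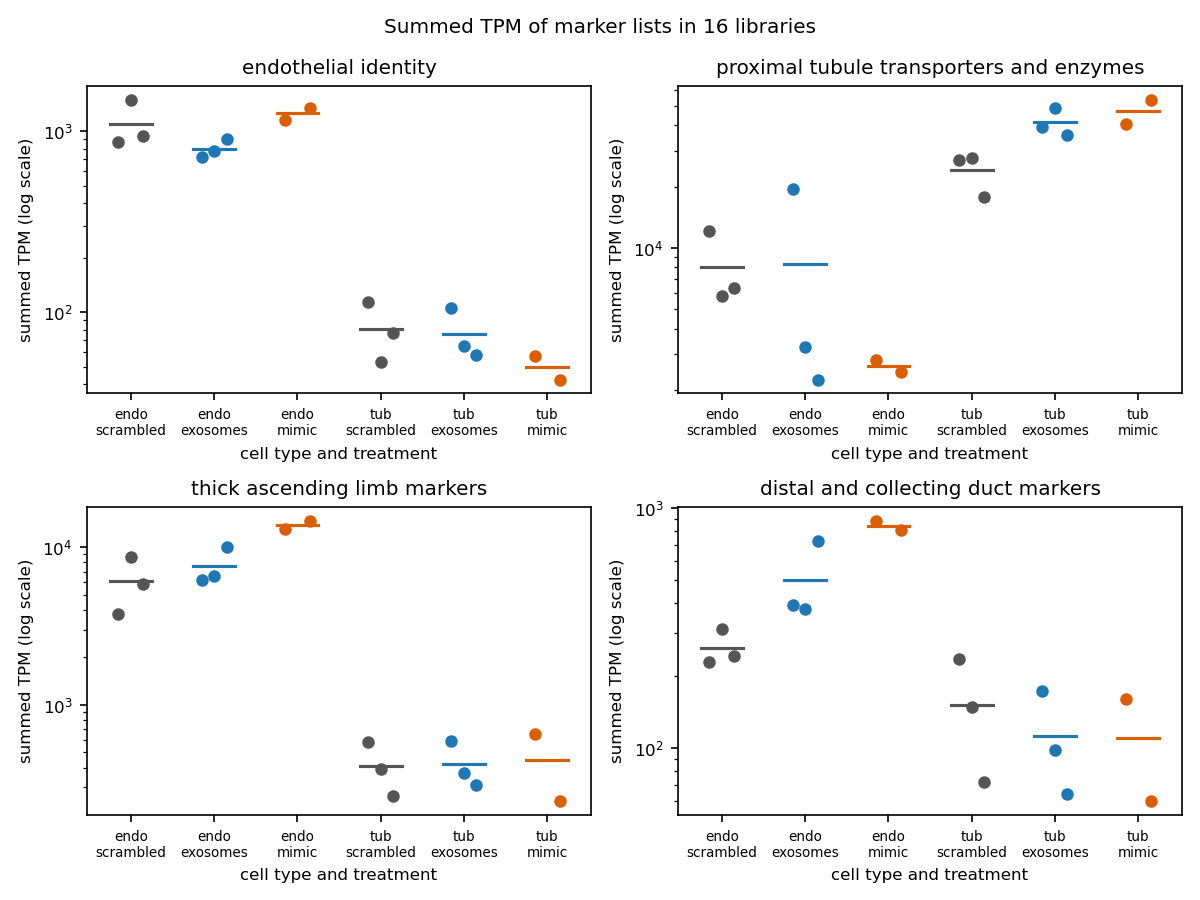
Summed TPM of the endothelial identity, proximal tubule, thick ascending limb and distal lists in each of the 16 libraries, on a log axis; points are libraries and bars are group means. In the endothelial libraries the thick ascending limb sum averaged 6077 TPM with scrambled miRNA and 13812 TPM with the mimic, above the endothelial identity sums of 1098 and 1251 TPM.

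The mimic carries the miR-486-5p sequence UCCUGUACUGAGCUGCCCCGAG, and its seed pairs with GTACAGG in messenger RNA. Foxo1, a transcription factor downstream of AKT (chromosome 3, 52268336 to 52353221), has 1 such site in a 3' UTR of 6243 bases, at 52347615 to 52347621. Foxo1 did not pass the test with the mimic: it differed from scrambled miRNA by 0.21 on the log2 scale in tubular cells (SE 0.25, adjusted p = 0.721) and by -0.04 in endothelial cells (SE 0.19, adjusted p = 0.936). The exosome comparisons gave -0.18 (adjusted p = 0.673) and 0.13 (adjusted p = 0.851). Across the 1182 endothelial genes with a site, the median log2 fold with the mimic lay 0.0365 below that of the 12749 genes without one, written as a difference of -0.0365 (jackknife SE over libraries 0.0176). This placed the site at percentile 17.9 among 419 other words of the same bases. For the 377 genes with the longer 8-base site the difference was -0.0697, for which no 8-base control words were run. In tubular cells the difference was 0.0196 (SE 0.0379, percentile 82.1, 1093 and 11547 genes). Under exosomes it was -0.0299 (percentile 45.8) and -0.00391 (percentile 94.7). Both jackknife SEs with the mimic pooled all libraries of a cell type, exosome libraries included, so they measure the spread only roughly. Genes are not independent replicates, so these percentiles describe the libraries. The 11 reported targets (10 measured in tubular cells) as a list did not pass in either mimic comparison (adjusted p = 0.0642 with median -0.25 in endothelial cells and 0.669 with median 0.08 in tubular cells), although 2 endothelial members fell when adjusted over the list alone.

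Exosomes were then compared with scrambled miRNA in tubular cells, where 406 genes rose and 359 fell of 14913 tested (edgeR, n = 3 and 3). Genes of the injured tubule fell. Havcr1, which encodes the kidney injury molecule KIM-1 (ENSMUSG00000040405, chromosome 11, 46735080 to 46779578), fell by 5.94 on the log2 scale (SE 1.16, adjusted p = 0.0326). Its level was 184 ± 186 TPM (SD, n = 3) with scrambled miRNA, spread over 5.64 to 376 TPM, and 2.5 ± 0.307 TPM (n = 3) with exosomes. Lcn2, the gene of the injury marker NGAL (chromosome 2, 32384633 to 32388252), fell by 4.09 (SE 0.97, adjusted p = 0.0469), from 29.8 ± 27.5 to 1.48 ± 0.957 TPM. Krt20, a keratin of damaged tubules (chromosome 11, 99428403 to 99438150), had no read in any exosome library and was at least 354-fold lower, taking 3 reads over the group as the floor. By the same floor Krt19 was at least 12.3-fold lower. Of the 24 measured injury genes, 12 fell and 12 did not pass, and 22 fell adjusted over the list alone. Sox9, a transcription factor of tubule repair, was among the former (-4.70, SE 0.95). The list median was -3.02, the same with Krt20 and Krt19 at their bounds.

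**Figure D2:**
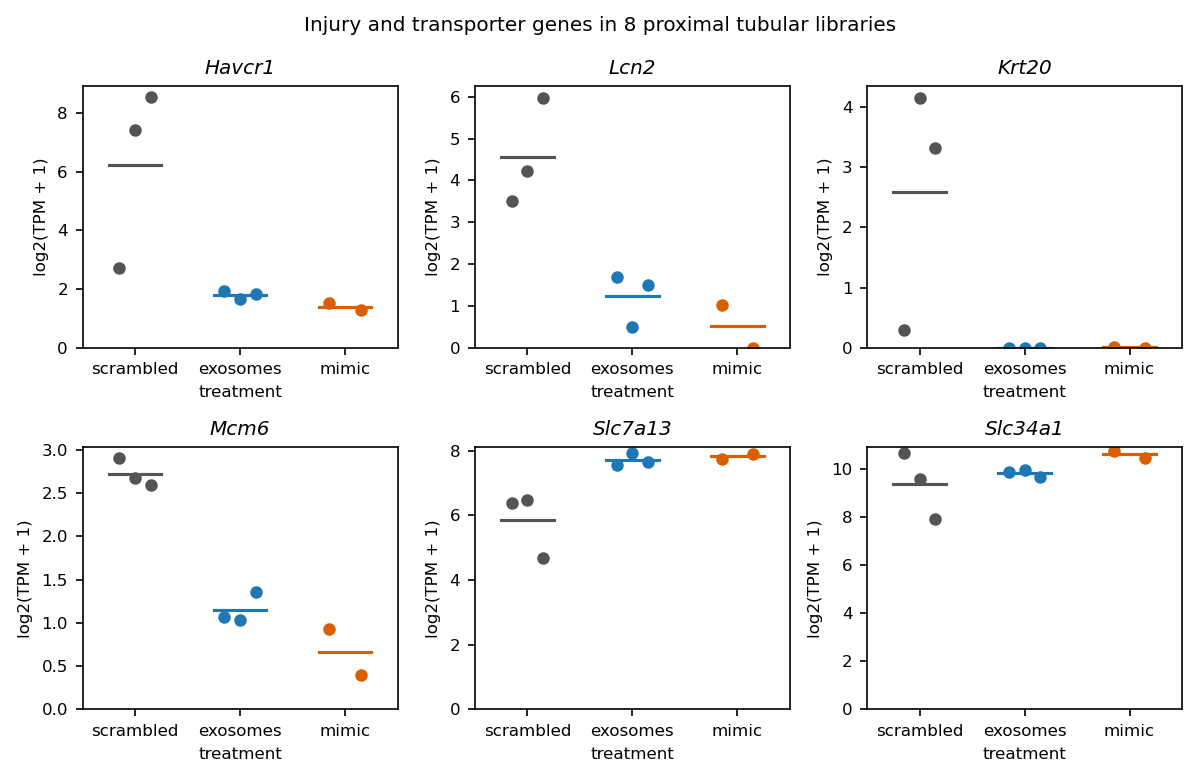
Expression as log2(TPM + 1) of Havcr1, Lcn2, Krt20, Mcm6, Slc7a13 and Slc34a1 in the 8 tubular libraries; each point is a library and each bar a group mean. Havcr1 spans 5.64 to 376 TPM in the 3 scrambled-miRNA libraries and stays at or below 2.80 TPM in the exosome and mimic libraries.

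Other lists moved with the injury genes in the exosome-treated tubular cells. Cell cycle genes fell in 6 of 16 cases (10 adjusted over the list alone, median -1.76), including the replicative helicase subunits Mcm3 (-2.34, SE 0.33), Mcm6 (-2.08, SE 0.26) and Mcm5 (-2.05, SE 0.33). Among matrix and TGF-beta genes 6 of 20 fell (13 adjusted over the list alone, median -1.04), such as the basement membrane chains Col18a1 (-2.07, SE 0.35) and Col4a1 (-1.16, SE 0.17). NF-kB and cytokine genes fell in 5 of 22 cases (8 adjusted over the list alone, median -1.19), with Relb at -2.64 (SE 0.54) and Icam1 at -1.80 (SE 0.28). Hmox1, the inducible heme oxygenase, fell by 1.98 (SE 0.32) with 3 other NRF2 genes of 19, Srxn1, Txnrd1 and Tkt (5 adjusted over the list alone, median -0.65). Cx3cl1 (-1.39, SE 0.23), Lcn2 and Icam1 fell among 15 endothelial activation genes (6 adjusted over the list alone, median -1.36), and the cell cycle inhibitor Cdkn1a (-2.09, SE 0.47) and Zmat3 among 24 p53 and apoptosis genes (4 adjusted over the list alone, median -0.47). The largest falls beyond the lists, in genes averaging at least 100 reads, were those of the urokinase receptor Plaur (-4.51, SE 0.86) and S100a6 (-4.25, SE 0.77).

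Among transporters and enzymes of the proximal tubule, 4 of 30 rose past the threshold with exosomes (5 higher and 1 lower adjusted over the list alone). A positive fold was seen in 21 of 30 (median 0.46, but 0.11 without scrambled-miRNA library 3). Slc7a13, an amino acid transporter of the late proximal tubule (chromosome 4, 19818725 to 19842218), rose by 2.08 (SE 0.40), from 65.4 ± 35.2 to 211 ± 29.9 TPM. Slc22a30 (1.64, SE 0.32), Kap (1.35, SE 0.32) and Cyp4b1 (1.14, SE 0.25) also rose, whereas Slc34a1 gave 0.38 (SE 0.47, adjusted p = 0.660). The top genes that rose were Inmt (2.23, SE 0.38), Slc22a19 (2.20, SE 0.34), Hnf4aos (2.20, SE 0.27), BC024386 (2.19, SE 0.32) and Akr1c14 (2.17, SE 0.29). Hnf4aos lies antisense to Hnf4a, and the Slc22a and Akr1c genes have close relatives, so their values depend on how reads were shared out. Echs1 (0.92, SE 0.15) and Etfa (0.70, SE 0.15) rose among fatty acid oxidation genes. Pfkfb3 (-1.17) and Pfkp (-1.15) fell and Bnip3 (0.75) rose among hypoxia and glycolysis genes. All 13 mitochondrially encoded genes had positive folds (median 0.88, 0 called, 0 adjusted over the list alone). Mitochondrial transcripts took 9.64, 10.8 and 14.3% of reads in the exosome libraries and 4.51, 9.73 and 7.81% in the scrambled-miRNA libraries.

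In this comparison 9 of 24 lists passed camera with the preset correlation: injury (adjusted p = 1.12e-10), cell cycle and matrix (1.36e-08 each), NF-kB (3.2e-06), mitochondrial (7.8e-05), proximal tubule and NRF2 (0.00247 each), endothelial activation (0.00498) and p53 (0.00527). None held with an estimated correlation (adjusted p = 0.263 to 0.685), and fry, which asks whether a list's genes move on balance one way, gave adjusted p = 0.0135 for cell cycle and matrix and 0.0819 for injury. The other 15 lists had adjusted p from 0.0528 for hypoxia and glycolysis to 0.822 for podocyte markers, with the reported miR-486-5p targets at 0.711 (median -0.08; 1 of 10 rose, and 1 rose and 2 fell adjusted over the list alone). Median and mean took opposite signs for the unfolded protein response (0.11 and -0.28) and for fatty acid oxidation (-0.01 and 0.06) and FoxO-responsive genes (0.11 and -0.03), and the interferon list had a median of 0.06 under a downward test. Among markers of other cells, fibroblast genes had a median of -1.02 (adjusted p = 0.0577) and thick ascending limb genes of 0.58 (adjusted p = 0.0577). Summed fibroblast TPM was 134 ± 64.7 with scrambled miRNA and 14.1 with exosomes. Mixed splits of the scrambled-miRNA and exosome libraries passed 7 to 12 lists by the same camera test, so the count of 9 does not set exosomes apart. The 765 calls became 1631 with DESeq2, 2014 with no low-count filter, 453 when the mimic libraries were left out and 29 with an offset for transcript length. Without scrambled-miRNA library 1, 2 or 3 there were 1005, 85 and 1335 calls, and without exosome library 1, 2 or 3 there were 12, 1 and 1. Leaving out scrambled-miRNA library 3 took the proximal tubule median to 0.11 and the NRF2 median to -0.15, both no longer passing, and the p53 median to -0.29. Endothelial activation was -0.83 without scrambled-miRNA library 2, and the mitochondrial list 0.56 without library 1.

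The mimic was compared with scrambled miRNA in the same tubular fit (n = 2 and 3), and 3 genes passed. Mcm6 fell by 2.98 (SE 0.31, adjusted p = 0.0289; chromosome 1, 128331590 to 128359664), from 5.64 ± 0.755 to 0.609 ± 0.410 TPM. Crispld2, a secreted protein gene (chromosome 8, 119992438 to 120052793), rose by 2.40 (SE 0.22, adjusted p = 0.0206), from 0.952 ± 0.213 to 4.34 ± 0.371 TPM. The predicted gene Gm6300 rose by 2.76 (SE 0.30, adjusted p = 0.0310). Havcr1 had a log2 fold of -6.56 (SE 1.43, adjusted p = 0.123) and stood at 1.64 ± 0.325 TPM (n = 2). Lcn2 gave -5.88 (SE 1.27, adjusted p = 0.123), Slc34a1 1.02 (SE 0.52, adjusted p = 0.362) and Pecam1 -0.01 (SE 0.19). The 3 calls stood beside 2427 genes at an unadjusted p under 0.05 and 728 calls by DESeq2, by which Havcr1 (adjusted p = 6.57e-05) and Lcn2 (0.0109) passed. With no low-count filter 1354 genes passed. None of the 3 passed with a length offset (adjusted p = 0.0817 to 0.121) or without the exosome libraries (0.0829 to 0.111), although the folds of Crispld2 (2.36 and 2.40), Mcm6 (-3.12 and -2.98) and Gm6300 (2.76 and 2.76) were near those above. Without mimic library 2 no gene passed (0.316 for Crispld2, 0.532 for Mcm6, 0.492 for Gm6300), without mimic library 1 Mcm6 did not (0.0635), and without scrambled-miRNA library 3 neither Mcm6 nor Gm6300 did (0.0528 each). Without scrambled-miRNA library 1 there were 494 calls, and Havcr1 (-7.11, adjusted p = 0.00173) and Lcn2 (-6.31, adjusted p = 0.0367) were among them.

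By list, 14 of 24 passed between mimic and scrambled miRNA in tubular cells, none with an estimated correlation (adjusted p = 0.143 to 0.645). Injury genes had a median of -3.77 (0 called of 24, 21 lower adjusted over the list alone; camera adjusted p = 8.74e-16), NF-kB and cytokine genes of -1.67 (0 of 22, 14 lower adjusted over the list alone), cell cycle genes of -1.39 (1 of 16, 8 lower adjusted over the list alone), matrix genes of -1.22 (0 of 20, 11) and endothelial activation genes of -1.48 (0 of 15, 8). Proximal tubule genes had positive folds in 28 of 30 cases (median 0.79; 12 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.13e-09). Their summed level was 24163 ± 5571 TPM with scrambled miRNA, 41445 ± 6572 with exosomes and 47015 ± 9055 with the mimic. Interferon response (median -1.07, 1 adjusted over the list alone), p53 (-0.43, 5) and NRF2 genes (-0.42, 0) passed as well. So did markers of macrophages (-0.98, 4), distal and collecting duct (-0.76, 1), fibroblasts (-0.98, 1), podocytes (-1.63, 0) and endothelium (-0.24, 0). By fry, cell cycle, matrix and endothelial activation kept 0.0205 each and injury had 0.0508. The other 10 had adjusted p from 0.0619 for immediate early and heat shock genes to 0.940 for FoxO-responsive genes, whose median was 0.16 and mean -0.11; the unfolded protein response had 0.03 and -0.64. Several medians depended on 1 library. Without mimic library 2 the distal (-0.04) and podocyte (-0.93) lists no longer passed, and fibroblast and matrix medians were -0.40 and -0.80. Without mimic library 1 the same lists stood at -4.54, -3.14, -3.21 and -1.88, and NRF2 (-0.31) and endothelial identity (-0.26) did not pass. Without scrambled-miRNA library 1 podocyte (-1.20) and identity (-0.14) lists did not pass. Without scrambled-miRNA library 2 identity was -0.43 and NF-kB -0.99. Without scrambled-miRNA library 3, NRF2 did not pass (-0.13), the proximal tubule median was 0.49 and p53 -0.23.

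Set directly against each other in tubular cells, mimic and exosomes differed in 0 of 14913 genes by edgeR, beside 1848 at an unadjusted p under 0.05 and 166 calls by DESeq2, 284 without the scrambled-miRNA libraries and 396 with no low-count filter. Havcr1 gave -0.61 (SE 1.15, adjusted p = 0.852), Lcn2 -1.79 (SE 1.23, adjusted p = 0.553) and Foxo1 0.39. Of 24 lists 10 passed, none with an estimated correlation (adjusted p = 0.815 or 0.838). Interferon response genes were lower with the mimic in 21 of 21 cases (median -1.42, camera adjusted p = 1.18e-05), mitochondrially encoded genes in 13 of 13 (-0.82, 0.000145) and endothelial identity genes in 21 of 22 (-0.60, 0.000293). PI3K-AKT-FoxO pathway members (0.30, 20 of 26 positive, 0.00216) and proximal tubule genes (0.31, 0.00416) were higher. Erythroid (-1.81), podocyte (-2.58) and macrophage (-0.78) markers and endothelial activation genes (-0.58) were lower, and the distal list passed downward with a mean of -0.30 and a median of 0.09. Interferon genes were higher in endothelial than in tubular libraries, so their fall cannot be told apart from less RNA of other cells with the mimic. Adjusted over the list alone, 3 erythroid markers and 1 each of the macrophage and distal markers were lower, and 0 genes of the other lists that passed. The other 14 lists had adjusted p from 0.0854 to 0.967. Among the latter, median and mean differed in sign for hypoxia (0.10 and -0.07) and NRF2 genes (0.11 and -0.01), and the test opposed the median for FoxO-responsive (-0.08), cell cycle (0.03) and matrix genes (-0.08). Only 4 lists passed without mimic library 2, where the distal list did not pass and had a median of 0.78 with the test upward. The proximal tubule (0.28), erythroid (-0.83), podocyte (-1.96), macrophage (-0.62) and endothelial activation (-0.29) lists did not pass there either. Without mimic library 1 there were 15, with medians of -3.31 for erythroid, -4.16 for podocyte, -1.21 for macrophage and -3.71 for distal markers. Without exosome library 1 the interferon median was -0.64, and podocyte (-1.38), macrophage (-0.09), distal (0.66) and endothelial activation (-0.41) lists did not pass. Without the scrambled-miRNA libraries the endothelial activation (-0.79, 0.0705), distal (0.10, 0.0851) and podocyte (-2.57, 0.0567) lists did not pass.

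In endothelial cells exosomes and scrambled miRNA differed in 0 of 16316 genes by edgeR (n = 3 and 3), against 1860 genes at an unadjusted p under 0.05 and 349 calls by DESeq2, 238 higher and 111 lower. With no low-count filter 896 passed, and without exosome library 1 or 2 there were 9 and 55 calls. Lcn2 had a log2 fold of -2.21 (SE 0.87, adjusted p = 0.386) at 376 ± 62.5 TPM with scrambled miRNA and 56.4 ± 70.3 TPM with exosomes. Havcr1 gave -3.26 (SE 1.29, adjusted p = 0.389), Slc34a1 0.59 (SE 0.72) and Pecam1 0.01 (SE 0.21). By camera with the preset correlation 13 of 27 lists passed, none with an estimated correlation (adjusted p = 0.317 to 0.702). Mixed splits of these libraries passed 5 to 14 lists with the preset correlation, so the count of 13 does not set exosomes apart. Injury genes as a list lay lower (median -0.94, 1 adjusted over the list alone, camera adjusted p = 1.46e-09, but 0.317 with an estimated correlation), with a summed level of 13199 ± 1109 TPM against 3495 ± 3135. NRF2 genes (median -0.59, 5 lower adjusted over the list alone), matrix genes (-0.43, 4), NF-kB and cytokine genes (-0.42, 1), p53 genes (-0.17, 0) and cell cycle genes (-0.52, 0) were lower too, with neutrophil (-1.26, 5 lower and 1 higher) and macrophage markers (-0.26, 0). Beside these, markers of other segments were higher: 15 of 15 distal and collecting duct markers (median 1.20, 14 adjusted over the list alone, camera adjusted p = 7.2e-10) and 10 of 10 thick ascending limb markers (1.21, 8). Mitochondrially encoded genes were higher in 13 of 13 cases (0.96, 12), lymphocyte markers in 17 of 17 (0.77, 0), and fatty acid oxidation genes had a median of 0.23 (1). Mitochondrial reads made up 9.08, 12.6 and 14.3% of scrambled-miRNA and 14.6, 23.8 and 23.0% of exosome libraries.

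The other 14 lists had adjusted p from 0.0514 for endothelial activation to 0.998 for immediate early and heat shock genes. Proximal tubule genes had a median of 0.40 under a downward test (adjusted p = 0.674), the immediate early median was 0.16 under a downward test, and median and mean differed in sign for podocyte (0.01 and -0.01), PI3K-AKT-FoxO (-0.08 and 0.02) and hypoxia genes (0.08 and -0.07). The reported miR-486-5p targets had a median of -0.10 (adjusted p = 0.166). Summed proximal tubule RNA varied within groups, from 5768 to 12104 TPM with scrambled miRNA and from 2246 to 19528 TPM with exosomes, and libraries 1 of both groups held the most. Without that pair, an alternative chosen after seeing the data, cell cycle (0.13), fatty acid oxidation (0.02), NF-kB (-0.09) and macrophage (-0.16) lists did not pass. The tests of cell cycle and fatty acid oxidation also turned direction, and the injury median was -0.59. Without exosome library 1, NF-kB (-0.17), cell cycle (-0.28), macrophage (-0.09) and fatty acid oxidation (0.07) lists did not pass, the last with its test turned downward. In that fit the injury median was -0.64 and the NRF2 median -0.96. Without exosome library 2 lymphocyte markers did not pass (0.14), and injury and NF-kB medians were -1.74 and -0.87. Cell cycle did not pass without exosome library 3 (-0.46) or scrambled-miRNA library 1 (-0.02), nor fatty acid oxidation without the latter (0.18), nor macrophages without scrambled-miRNA library 2 (-0.13). The p53 median was -0.30 without scrambled-miRNA library 2 and -0.10 without exosome library 3.

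With the mimic, endothelial cells again had 0 of 16316 genes past the threshold against scrambled miRNA by edgeR (n = 2 and 3). There were 3176 genes at an unadjusted p under 0.05 and 1254 calls by DESeq2, 654 higher and 600 lower. The exosome-free fit gave 1494, the fit with no low-count filter 2038 and the fit without the pair with high proximal tubule RNA 957. Lcn2 gave -4.70 (SE 1.16, adjusted p = 0.0845), down to 13.1 ± 8.06 TPM, and Havcr1 -7.20 (SE 1.91, adjusted p = 0.0980). Both passed by DESeq2, in the exosome-free fit and with no low-count filter, and Lcn2 also without the pair. Slc34a1 gave -1.22 (SE 0.83) and passed with no low-count filter only, and Pecam1 0.18 (SE 0.23). Of 27 lists 13 passed, none with an estimated correlation (adjusted p = 0.404 to 0.783). Distal and collecting duct markers were higher in 15 of 15 cases (median 1.55, 15 adjusted over the list alone, camera adjusted p = 1.27e-09) and thick ascending limb markers in 10 of 10 (1.79, 9), at a summed 13812 ± 1012 TPM against 6077 ± 2427. Proximal tubule genes were lower in 27 of 30 cases (-1.65, 1), at 2629 ± 262 against 8082 ± 3497 TPM. NRF2 genes (-1.24, 13 lower adjusted over the list alone, adjusted p = 1.34e-09) and injury genes (-1.58, 13) were lower, as were p53 (-0.34, 0), NF-kB (-0.59, 2), cell cycle (-1.04, 0) and matrix genes (-0.31, 6 lower and 2 higher) and neutrophil markers (-1.04, 1 lower and 1 higher). NRF2 genes were higher in tubular than in endothelial libraries, and proximal tubule RNA fell here. The lower NRF2 level therefore cannot be assigned to endothelial cells. Lymphocyte markers (0.87), endothelial identity (0.31, 21 of 22 positive) and mitochondrial genes (0.37) were higher, with 0 adjusted over the list alone. By fry the adjusted p was 0.0660 for distal, thick ascending limb and NRF2 lists. The other 14 had 0.0642 to 0.857, including FoxO-responsive genes (0.0755, 5 higher adjusted over the list alone) and hypoxia genes with a median of 0.07 and a mean of -0.05.

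Single libraries decided some of these medians. Without scrambled-miRNA library 1, cell cycle (-0.34), endothelial identity (0.11) and mitochondrial (0.16) lists did not pass, and the same 3 failed without the pair with high proximal tubule RNA (-0.29, 0.15 and 0.20). Without mimic library 1, cell cycle (-0.75), mitochondrial (0.22) and neutrophil (-0.72) lists did not pass and NF-kB stood at -0.37. Without mimic library 2, identity (0.22) and lymphocyte (-0.03) lists did not pass and cell cycle stood at -1.68. Identity was 0.51 without scrambled-miRNA library 2. Mimic against exosomes in endothelial cells gave 0 calls, 661 genes at an unadjusted p under 0.05, 5 calls by DESeq2 and 661 with no low-count filter; Lcn2 gave -2.49, Havcr1 -3.94 and Slc34a1 -1.81, each at an adjusted p of 0.988. Of 27 lists 10 passed, none with an estimated correlation (adjusted p = 0.674 to 0.822). Proximal tubule genes were lower in 28 of 30 cases (median -1.95, camera adjusted p = 2.16e-09, but -0.38 without exosome library 1), mitochondrial genes in 13 of 13 (-0.55), and NRF2 (-0.50), interferon (-0.30) and injury genes (-0.64) had lower medians. Endothelial identity (22 of 22, 0.34), thick ascending limb (10 of 10, 0.58), distal (15 of 15, 0.30), fibroblast (0.41) and immediate early genes (0.22) were higher. Median and mean differed in sign for fatty acid oxidation (0.05 and -0.13), matrix (0.01 and -0.03), endothelial activation (0.08 and -0.06) and macrophage genes (-0.03 and 0.04), none of which passed. These 10 lists had 0 genes adjusted over the list alone, and the other 17 had adjusted p = 0.0617 to 0.755. Without exosome library 1 immediate early (-0.09), distal (0.04), interferon (-0.20) and fibroblast (0.27) lists did not pass, and the immediate early test turned direction. Without exosome library 2 the injury list turned (0.12) and did not pass. Without mimic library 1 distal (0.17), interferon (-0.07), injury (-0.53) and immediate early (0.05) lists did not pass. Thick ascending limb and distal medians were 0.94 and 0.78 without exosome library 3, and interferon -0.59 without mimic library 2.

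Whether the treatments differed in effect between cell types was tested with interaction terms over all 16 libraries. By edgeR 0 of 17143 genes passed for exosomes, with 1333 at an unadjusted p under 0.05, 31 calls by DESeq2 and 503 with no low-count filter. For the mimic 0 passed, with 2650, 595 and 1716. Without endothelial exosome library 1 there were 76 calls for exosomes, and without tubular mimic library 1 there were 105 for the mimic. Havcr1 gave 2.67 (SE 1.77, adjusted p = 0.735) and -0.64 (SE 2.03, adjusted p = 0.927), and Foxo1 0.28 and -0.26. For exosomes 6 of 27 lists passed, between 4 without endothelial exosome library 2 and 10 without tubular exosome library 3, and for the mimic 15, down to 7 without tubular mimic library 2. None held with an estimated correlation (adjusted p = 0.840 for exosomes, 0.594 to 0.716 for the mimic). The other lists had 0.0906 to 0.848 and 0.0587 to 0.978. Among these, median and mean differed in sign for reported targets (0.03 and -0.21), unfolded protein response (-0.03 and 0.34) and macrophage markers (-0.15 and 0.21) with exosomes. With the mimic they did for PI3K-AKT-FoxO (-0.12 and 0.04) and fatty acid oxidation genes (0.16 and -0.01). The test opposed the median for neutrophil (1.65), lymphocyte (-0.25) and mitochondrial lists (0.10) with exosomes and platelet markers (0.07) with the mimic.

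The response to injury without treatment was read from the authors' deposited tables, which count the first-named group over the second. Folds in all of these tables appear shrunken toward 0, so their sizes are not comparable with the folds fitted here. In the authors' deposited table for tubular cells, 1946 genes were higher in untreated injury than in sham and 1460 lower. In the authors' deposited table Krt20 was 11.53 log2 units higher (adjusted p = 4.31e-08), Lcn2 6.84 (1.62e-06), Havcr1 5.19 (1.25e-05) and Cdkn1a 4.75, while the transporter Slc7a13 (-1.81) and the endocytic receptor Lrp2 (-1.63) were lower. From the same authors' deposited table, injury genes were higher in 18 of 24 cases (21 adjusted over the list alone, median 3.17), with 12 p53 genes, 11 NF-kB genes and 9 matrix genes, and 10 of 30 proximal tubule genes were lower. There 9 of 26 lists passed, none with an estimated correlation (injury adjusted p = 0.0626). In endothelial cells the authors' deposited table gave 638 genes higher and 215 lower, with Saa1 (10.81), Krt20 (9.75), Lcn2 (7.20, adjusted p = 6.06e-19), the adhesion molecule Selp (6.32) and Havcr1 (4.86) higher. There, in the authors' deposited table, 21 of 24 injury genes (median 2.53), 9 of 11 neutrophil markers (3.23), 12 NF-kB, 8 matrix, 7 endothelial activation and 5 p53 genes and the reported targets Mmp19 (3.02) and Smad1 (1.31) were higher. Of 19 lists that passed on the authors' deposited table, 7 held with an estimated correlation, injury at an adjusted p of 0.000223 and the reported targets at 0.0165. The endothelial libraries analysed here carried tubule RNA, so changes in tubule injury genes cannot be assigned to endothelial cells. The same holds for NRF2 genes, which were higher in tubular than in endothelial libraries.

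Each treated group was set against untreated injury and, for exosomes and mimic, against sham in further tables; the untreated and sham libraries come from an earlier deposit, so these tables also compare 2 deposits. In tubular cells the authors' deposited table of untreated injury against exosomes called 3398 genes higher and 2570 lower in untreated injury, that against the mimic 2583 and 1610, and that against scrambled miRNA 1866 and 1139. Havcr1 was higher in untreated injury by 4.17 (adjusted p = 0.000136) and 5.03 (8.56e-05) against exosomes and mimic in the authors' deposited tables, and Lcn2 by 6.99 and 8.84. Against scrambled miRNA the authors' deposited table gave -0.17 for Havcr1 (adjusted p = 0.493) and 0.44 for Lcn2 (0.0509). As the deposited folds appear shrunken, values near 0 here and against sham do not show equal levels. Injury genes higher in untreated injury numbered 23 of 24 against exosomes, 22 against mimic and 6 against scrambled miRNA in the authors' deposited tables, at adjusted p = 0.0564, 0.0169 and 0.542 with an estimated correlation. In the authors' deposited tables, the lists that passed numbered 17, 18 and 14, and matrix, endothelial activation and hypoxia lists held against exosomes (0.00677, 0.0363 and 0.00798) and, with the injury and NF-kB lists, against the mimic. Against sham, the authors' deposited table for exosomes had 993 genes higher and 789 lower, with Havcr1 at 0.08 (adjusted p = 0.637) and Lcn2 at -0.01 (0.968), and 8 immediate early and heat shock genes lower (median -0.46). That for the mimic, again the authors' deposited table, had 8 and 176, with Havcr1 at 0.00 (0.999), Lcn2 at -0.01 (0.720) and Nr4a1 at -2.78 (8.16e-05). On the authors' deposited tables against sham, 8 of 25 and 14 of 27 lists passed, none with an estimated correlation.

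**Figure D3:**
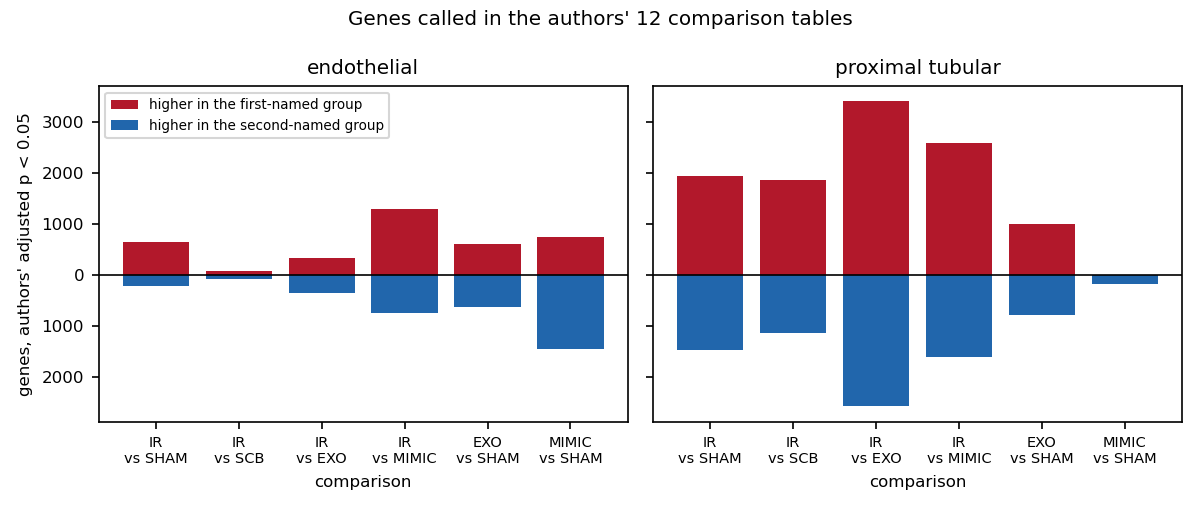
Genes with an adjusted p under 0.05 in each of the 12 comparison tables deposited by the authors; bars upward count genes higher in the first-named group and bars downward genes higher in the second. Tubular untreated injury against exosomes has the tallest bars, with 3398 and 2570 genes, and tubular mimic against sham has 8 and 176.

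In endothelial cells the authors' deposited tables called 327 genes higher and 348 lower in untreated injury than with exosomes, 1282 and 750 against the mimic, and 70 and 84 against scrambled miRNA. NRF2 genes were higher in untreated injury against exosomes (9 of 19, median 1.05) and against the mimic (13 of 19, median 1.5) in the authors' deposited tables, at adjusted p = 0.0741 and 0.0476 with an estimated correlation. In the authors' deposited table against the mimic, 24 of 29 proximal tubule genes were higher (median 2.29) and 8 of 10 thick ascending limb markers lower (-1.54), both at 0.140 with an estimated correlation. Lcn2 was higher in untreated injury by 1.73 (adjusted p = 0.0471) and 4.51 (2.76e-06) in the authors' deposited tables against exosomes and mimic, and by 0.01 (0.983) against scrambled miRNA. Against sham, the authors' deposited tables had 616 genes higher and 620 lower with exosomes and 742 and 1439 with the mimic. Macrophage markers were higher in 13 of 18 (median 2.25) and 14 of 18 cases (2.20) in the authors' deposited tables, with adjusted p = 0.0400 and 0.111 with an estimated correlation, and the chemokine Ccl2 by 5.02 and 4.29. Proximal tubule genes were lower in 15 and 26 of 29 cases (medians -1.37 and -3.59) in the authors' deposited tables, at 0.127 and 0.0542 with an estimated correlation. In these authors' deposited tables, the lists that passed numbered 17, 14 and 13 against exosomes, mimic and scrambled miRNA, of which 0, 2 and 1 held with an estimated correlation, and 18 and 18 passed against sham, of which 5 and 0 held. In lists that did not pass, the authors' deposited tables gave a median fold opposite to the test within 0.07 of 0, except the unfolded protein response of tubular cells at -0.13 and -0.09 in untreated injury against exosomes and mimic.

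Injury genes taken from the tables of untreated injury against sham were followed in libraries of neither of those groups, although the deposited tables had been normalized over all groups together. In tubular cells the 288 tested genes higher in injury had a median log2 fold of -1.05 with exosomes and -1.02 with the mimic against scrambled miRNA, with 5.21 and 4.51% of them positive. The 296 genes lower in injury had medians of 0.65 and 0.73, with 93.2 and 92.9% positive. With exosomes 80 of the former fell and 52 of the latter rose (23 and 30 with a replicate block), and with the mimic 0 and 1 (0 and 2). In endothelial cells the 296 genes higher in injury had medians of -0.79 and -1.13, and the 135 lower in injury 0.88 and 0.42. With an estimated correlation, camera gave p = 0.0450 and 0.0943 for tubular exosomes, 0.0389 and 0.0609 for tubular mimic, 0.0547 and 0.0262 for endothelial exosomes and 0.0700 and 0.112 for endothelial mimic, for genes higher and lower in injury. The corresponding fry values were 0.00389 and 0.0102, 0.00595 and 0.0145, 0.0258 and 0.00612, and 0.0159 and 0.0377. With a replicate block the camera values under 0.05 became 0.0870, 0.0912 and 0.0823 in that order, and the last fry value became 0.110. Endothelial medians under exosomes ranged from -1.19 without exosome library 2 to -0.58 without exosome library 1 for genes higher in injury, and the genes lower in injury had 0.45 without exosome library 1.

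The exosome and mimic effects were finally compared with each other across genes. Their log2 folds against scrambled miRNA correlated at r = 0.704 in tubular and 0.673 in endothelial cells. In 20 simulations of unchanged groups that shared 3 simulated controls, r was 0.459 and 0.454. All simulated libraries were drawn from the scrambled-miRNA mean with genes independent, so they do not hold the real controls' shared variation. The covariance was 0.581 against 0.145 simulated in tubular cells and 0.497 against 0.15 in endothelial cells. Of the 3 genes called with the mimic in tubular cells, Crispld2 and Gm6300 also rose and Mcm6 also fell with exosomes. Independent lists would share 0.0544 and 0.0241 genes, but these lists share their controls, and shared calls were not simulated. The 3 control libraries cannot be split into parts of 2, so part of the excess may come from shared controls. Across the authors' deposited tables for tubular cells, z scores of untreated injury against sham correlated with those of untreated injury against exosomes (r = 0.749), mimic (0.830) and scrambled miRNA (0.671). All 4 of the authors' deposited tables share the untreated libraries, and unchanged groups with those libraries shared gave 0.496, 0.442 and 0.501 in simulation.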

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

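The tests of the tubular injury and endothelial loop patterns below, and the splits of the samples for the count of genes in tubular cells and for the lists, were chosen after the results were seen. The 2 tests of the deposits and the other splits were chosen before.

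By camera with the preset correlation, 6 lists passed a test of the interaction for exosomes (endothelial minus tubular, median log2). Distal and collecting duct markers differed by 1.86, injury genes by 1.45, cell cycle genes by 1.07, NF-kB and cytokine genes by 0.80, matrix genes by 0.55 and proximal tubule genes by -0.12. With an estimated correlation the adjusted p of each was 0.840, and by fry it was 0.620 to 0.788. Leaving out 1 library ended the call of injury genes in 3 fits, of NF-kB genes in 4 and of proximal tubule genes in 5. The proximal tubule median ran from -1.60 without endothelial exosome library 1 to 0.28 without endothelial scrambled-miRNA library 1, and the injury median was 0.24 and the NF-kB and cell cycle medians 0.41 and 0.68 without endothelial exosome library 2. Without endothelial scrambled-miRNA library 1, cell cycle was 1.80 and matrix 0.34.

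For the mimic, 15 lists passed the same test. Distal and collecting duct markers (2.53), podocyte (1.75), lymphocyte (1.48), thick ascending limb (1.47), fibroblast (1.46) and macrophage markers (1.13) differed upward, as did NF-kB (1.20), matrix (1.15), interferon (1.08), endothelial activation (1.07), immediate early (0.95) and endothelial identity genes (0.74). Proximal tubule genes (-2.47), NRF2 genes (-0.88) and the reported miR-486-5p targets (-0.26) differed downward. With an estimated correlation their adjusted p was 0.594 to 0.716, and by fry it was 0.153 to 0.456. Several lists that passed for exosomes or the mimic mark other cells, whose RNA the endothelial libraries carried. These differences therefore cannot be assigned to a response of endothelial cells.

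Single libraries moved these mimic differences. Without tubular mimic library 1, distal markers stood at 5.93, fibroblast at 3.55, podocyte at 3.49, lymphocyte at 2.42, NF-kB at 1.88 and immediate early genes at 1.60. Without tubular mimic library 2, distal markers stood at 1.56, and fibroblast (0.61), podocyte (1.03), matrix (0.43), immediate early (0.38), macrophage (0.76), lymphocyte (0.94), NF-kB (0.94) and endothelial activation lists (0.65) no longer passed. Without endothelial mimic library 2, macrophage (0.59), lymphocyte (0.87), endothelial activation (0.61) and NF-kB lists (0.82) no longer passed. The reported miR-486-5p targets no longer passed in 6 of the fits without 1 library (adjusted p = 0.0637 to 0.186), macrophage markers in 6, immediate early genes in 5, podocyte markers in 4, and NF-kB and endothelial activation genes in 3 each. NF-kB was 0.71 without tubular scrambled-miRNA library 2, identity 0.47 without tubular scrambled-miRNA library 1, and NRF2 -0.53 without endothelial scrambled-miRNA library 3.

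For exosomes the real split gave 0 genes with an interaction, so 30 of 30 splits have as many by construction and the count tests nothing; the highest other gave 2. For the cell type, only 1 of 30 splits, the real one with 11355 genes, gave as many, and the highest other gave 1. The other splits mixed endothelial and tubular libraries, which widens the spread within their groups and keeps their counts low. As 1 of 30 is also the smallest share these splits can give, no conclusion about chance is drawn.

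Injury genes lay lower in tubular cells with exosomes (median -3.02) and the mimic (-3.77) than with scrambled miRNA. If 1 scrambled-miRNA library carried this, leaving it out would bring the median near 0, but the highest medians were -2.34 with exosomes and -2.83 with the mimic, which argues against it. RNA of other cells in the scrambled-miRNA libraries would lower their markers: of 6 lists the lowest median was -1.02 with exosomes (fibroblast and pericyte, SE 0.450, 3 of 6 negative) and -1.63 with the mimic (podocyte, SE 0.419, 5 of 6 negative), each within 2 standard errors of the injury median divided by 2 (-1.51 and -1.88). These standard errors are over list members, which are not independent replicates. Summed fibroblast TPM was 134 with scrambled miRNA, 14.1 with exosomes and 8.06 with the mimic, so RNA of other cells cannot be told apart. A smaller injury with treatment stays untested, and a difference in the injury at surgery could give the same values.

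The endothelial mimic libraries held more RNA of loop and duct markers and less of proximal tubule markers. A lower share of endothelial cells would raise both, but the proximal median minus the loop median was -3.44. Its SE of 0.465 is over list members, which are not independent replicates. In fits without 1 library the proximal median stayed between -1.84 and -1.21. The loop median stayed between 1.43 and 2.10, which argues against a lower endothelial share as the whole cause. More loop cells of one kind would raise the 10 loop markers alike. Their folds ran from 0.63 to 4.04, and 3 lay more than 2 standard errors from the list median. The limit of 3 was set after the results were seen and equals the number found, so no conclusion is drawn from it. More loop cells, a change within them or a change in the mix of segments collected all stay open, and no biological explanation was tested.

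In tubular cells the authors' deposited table gives 1866 genes higher in untreated injury than with scrambled miRNA and 1139 lower. The untreated and sham libraries come from another deposit than the treated ones. If the deposits differ, the same genes should lie the other way in exosomes against sham, and they do: the median z was -1.19 (SE over genes 0.0409, 81.9% negative) for the 1866 and 1.38 (SE over genes 0.0694, 19.9% negative) for the 1139. This is consistent with a difference between deposits contributing to these calls. In untreated injury against sham, within the earlier deposit, the same genes had median z of 2.60 and -2.19, which a difference between deposits does not predict, although both comparisons share the untreated libraries. An effect of treatment or injury stays open.

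With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In tubular cells the real split gave 765 genes and the highest other 1 (1 of 10 as large), 9 lists against 12 (8 of 10), and a signature difference of 1.71 against 1.19 (1 of 10). In endothelial cells it gave 0 genes, so 10 of 10 splits have as many by construction and that count tests nothing. There the real split gave 13 lists against 14 (3 of 10), and 1.66 against 1.36 (1 of 10). The other splits passed 7 to 12 lists in tubular and 5 to 14 in endothelial cells. Counts of lists at the preset correlation therefore do not set the real split apart.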

How the results depend on the processing

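The alternatives were fixed before the data were examined, except 2 that were chosen after seeing the data: fold over standard error for the deposited tables, where it is the choice made first, and leaving out the endothelial pair with high proximal tubule RNA. Of the counts and set values, 313 stayed near their value (counts within 1.5 times) and 50 moved. Only lists that passed in the main fit were followed: 1038 of their tests still passed, 114 no longer passed, and 7 reversed direction and no longer passed. Lists that newly passed are not in these counts. Some fits had more lists passing, such as 13 in place of 9 for tubular exosomes against scrambled miRNA without exosome library 3. Of single genes 3248 kept their side, 274 no longer passed and 27 newly passed. RLE normalization, a base mean of at least 10, adjustment over every gene of a deposited table, and the larger or unfiltered injury signatures changed counts by less than 1.5 times and kept the direction of each injury signature. Where no cause is named, the cause was not tested.

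With no filter on low counts there were 896, 2038 and 661 calls in endothelial cells (exosomes and mimic against scrambled miRNA, mimic against exosomes), 2014, 1354 and 396 in tubular cells, and 503 and 1716 for the interactions of exosomes and mimic. The prior degrees of freedom rose from 4.07 and 4.35 to infinity there, which makes the test less cautious. DESeq2 gave 349, 1254, 5, 1631, 728, 166, 31 and 595 in the same order. With only the 2 groups compared, calls were 1494 for endothelial mimic, 453 for tubular exosomes and 0 for tubular mimic against scrambled miRNA, and 284 for tubular mimic against exosomes. An average transcript length offset left 29 calls for tubular exosomes and 0 for tubular mimic, and of the 44 genes named for tubular exosomes 39 no longer passed. Without the pair with high proximal tubule RNA, endothelial mimic against scrambled miRNA gave 957.

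Deviations from group means gave little sign that the numbers in the titles pair the libraries: 1 of 7 same-number pairs in each cell type correlated above 0.1 (-0.0114 to 0.241 endothelial, -0.0702 to 0.226 tubular), as did 0 of 7 by library number (-0.108 to 0.0881). In 7 of 14, 4 of 14 and 1 of 14 comparisons a library correlated best with its own number, and no chance share was computed. The deviations of the 2 libraries of a mimic group mirror each other, so these values cannot exclude pairing. With a replicate block there were 661 calls for endothelial mimic, 286 for tubular exosomes (268 shared) and 8 for tubular mimic (2 shared) against scrambled miRNA; 9 list calls ended, 2 named genes of endothelial mimic newly passed, and no other count moved by over 1.5 times. For the injury signature the block took camera with an estimated correlation from 0.0450 to 0.0870 (tubular exosomes, genes higher in injury), from 0.0389 to 0.0912 (tubular mimic, the same genes) and from 0.0262 to 0.0823 (endothelial exosomes, genes lower in injury), and the genes called in the first from 80 to 23. For endothelial mimic it took fry for genes lower in injury from 0.0377 to 0.110, with 17 of them called higher and 46 of the genes higher in injury called lower, from 0 and 0. Of the differences between cell types, the block ended the calls of NF-kB genes for exosomes (median 0.61, camera 0.0583) and, for the mimic, of immediate early (0.16, 0.570), matrix (0.45, 0.160), podocyte (0.84, 0.304) and fibroblast (0.57, 0.193) lists. The other 4 were fatty acid oxidation in endothelial exosomes (0.20, 0.0581), NRF2 genes in tubular mimic (-0.29, 0.0803), both against scrambled miRNA, and proximal tubule (0.19, 0.0884) and endothelial activation genes (-0.66, 0.0758) in tubular mimic against exosomes.

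When each library was left out in turn, calls ran from 0 to 55 for endothelial exosomes, 1 to 1335 for tubular exosomes, 0 to 494 for tubular mimic, 0 to 1 for tubular mimic against exosomes, and 0 to 76 and 0 to 105 for the interactions. Lists passing ran from 4 to 15 for tubular mimic against exosomes, 4 to 10 for the exosome interaction and 7 to 16 for the mimic interaction. Fewer libraries and a single mimic library, assumed to vary like the other groups, are part of these fits.

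Lists that reversed did so without 1 or 2 libraries, and none passed in the new direction. In endothelial exosomes against scrambled miRNA, fatty acid oxidation ran from 0.0734 to 0.340, with the test turned at 0.0734 (without exosome library 1) and at 0.0239 (without the pair), and cell cycle was 0.132 without the pair. In endothelial mimic against exosomes, immediate early genes ran from -0.0933 to 0.416 (-0.0934 without the pair) and injury genes from -0.910 to 0.118. In tubular mimic against exosomes, distal markers ran from -3.71 to 0.780.

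For the seed sites, 8mer only moved the endothelial difference from -0.0365 to -0.0697 (377 genes), and leaving out 1 library gave -0.0467 to -0.0257, and 0.0065 to 0.0546 in tubular cells. By fold over standard error, 4 lists passed in tubular exosomes against sham instead of 8, and 8 in tubular mimic against sham instead of 14. No alternative varied depth, so what depth limits was not tested.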

Other observations

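Respiratory complex I is the first enzyme of the electron transport chain. In tubular cells with exosomes all 36 measured nuclear subunits had positive folds against scrambled miRNA, 14 of them past the threshold (median 0.54; fry adjusted p = 0.0196, camera adjusted p = 0.393 with an estimated correlation). In endothelial cells with exosomes the median was 0.58 with 36 of 36 positive and 0 past the threshold (fry adjusted p = 0.0232; 0.258 with an estimated correlation). The mimic gave 0.70 in endothelial cells with 35 of 36 positive and 0 past the threshold (fry adjusted p = 0.0217; 0.429) and 0.07 in tubular cells with 22 of 36 (fry adjusted p = 0.719). Mitochondrially encoded genes had medians of 0.88 in tubular and 0.96 in endothelial cells with exosomes. With the mimic their medians were 0.37 in endothelial and 0.01 in tubular cells. As a list they did not hold with an estimated correlation in any of these comparisons, and none passed singly. The endothelial mimic median was 0.16 without scrambled-miRNA library 1 and 0.22 without mimic library 1. Whether the difference is particular to complex I was not tested. These families of genes were chosen after seeing the data, and p-values were adjusted over the families of a comparison.

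The MCM helicase, which opens DNA for replication, fell in tubular cells with exosomes in 6 of 6 subunits (median -1.94, fry adjusted p = 0.0191; 0.393 with an estimated correlation). With the mimic 6 of 6 had negative folds and 1 passed (median -1.92, fry adjusted p = 0.0234; 0.232). Mcm2, Mcm3, Mcm5 and Mcm6 also belong to the cell cycle list, so this is not a separate finding from that list. Tubulins had medians of -1.53 with exosomes (5 of 10 fell, 0 positive, fry adjusted p = 0.0196; 0.393 with an estimated correlation) and -1.63 with the mimic (0 positive of 10, fry adjusted p = 0.0338; 0.232). UDP-glucuronosyltransferases had a median of -2.86 in endothelial mimic libraries with 0 of 11 positive (fry adjusted p = 0.155), in libraries where proximal tubule markers also fell (median -1.65).

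The tubular libraries lay on a gradient. On the first principal component (35.2% of variance) the scrambled-miRNA libraries were at -19.0, -50.8 and -83.4, the exosome libraries at 10.4, 36.0 and 36.8 and the mimic libraries at 19.1 and 50.8. In endothelial cells (36.5%) the values were -74.8, -22.5 and -44.1, then -23.6, 6.64 and 49.4, then 56.6 and 52.4, and exosome library 1 stood apart on the second component (18.2%) at 77.5.

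Across the deposited tables the z scores of untreated injury against sham and exosomes against sham, which share the sham libraries, correlated at r = 0.555 in endothelial and 0.0372 in tubular cells. Their covariance was 1.34 and 0.135, where unchanged groups with a shared control gave 0.499 and 0.520 in simulation. With the mimic the covariance was 1.18 in endothelial and -0.0106 in tubular cells (0.448 and 0.431 simulated). The tubular covariance thus lay below that of the simulated unchanged groups, and the endothelial covariance above it. The simulation gave all libraries the same spread and held no difference between deposits. The treated libraries come from another deposit than the sham and untreated ones, so these values cannot separate an effect of treatment from a difference between deposits.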
